A study of Mus musculus with 8 samples.

How the data were processed

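The series measured messenger RNA in pieces of mouse liver. Libraries were made after poly-A selection and sequenced in pairs on an Illumina NovaSeq, per the labels' protocols. The 8 libraries fall into 2 groups by their labels: 3 from untreated C57BL/6J mice and 5 from C57BL/6J mice that received a TAZ S89A construct by HTVI and 30 injections of carbon tetrachloride (CCl4). HTVI stands in this field for hydrodynamic tail vein injection, which delivers plasmid DNA mainly to hepatocytes. The labels number the libraries within each group, and those numbers name the replicates here. The labels assign the controls to one library project and the treated libraries to another, and each control's label also carries a second sample identifier. The labels do not spell out that each library came from a separate mouse, so p-values measure the spread between these samples, which may be technical in part.

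The deposited table holds a normalised count signal per gene and library, that is, the authors' gene-level counts divided by scaling factors. The name of the table deposited by the authors gives kallisto for quantification and DESeq2 for normalisation. The authors' use of DESeq2 and the mm10 genome build are also stated, per the submitters' processing notes. Tool versions, the transcript annotation and any filter on genes are not given in the sources used here. The values are neither whole counts nor scaled to a common total. The totals of the normalised values were 29.8 to 35.1 M in the controls and 12.4 to 14.2 M in the treated libraries.

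Whole reads were searched for in the low values. The most frequent step between values below 10 was taken as the value of 1 read, which gave 0.365 to 1.90 per library. Only 54.8% to 66.8% of values below 10 lay within 0.03 of a whole multiple of that step, so whole reads were not recovered and no count model was run. The step puts the depth at about 18.5 to 24.8 M reads in the controls and 12.4 to 33.9 M in the treated libraries, as an estimate. Pairs of libraries of the same group differed by 4.46 to 31.5 times the variance that counting noise gives, so no 2 libraries matched within counting noise, which does not exclude that some came from the same mouse.

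Of the 35204 gene symbols in the table, 12579 were at 0 in all libraries, and 14171 had a mean of at least 10 over the 8 libraries and were tested. Values were transformed as log2(value + 1), and fold changes are on that scale, which understates the change of low genes. Groups were compared with limma (version 3.58.1, R 4.3.3) with a trend in the prior variance, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. No covariate was used, because the library project coincides with the group. Positions were taken from GENCODE release M21, which describes the same build, where 34641 of the symbols were found. Genes of near-identical families such as the major urinary proteins (Mup) can share reads, so their single-gene values are uncertain, and antisense or overlapping partners were not resolved.

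Before the data were examined, 44 gene lists for pathways, cell types, RNA quality and sex-biased liver genes were fixed from textbook knowledge, together with the tests and the processing alternatives. Each list was tested with limma's camera, which compares the list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. Camera p-values were adjusted over the 43 lists with more than 1 tested gene. They refer to the deposited scaling unless another is named with them, also where counts at another scaling stand just before. The mean log2 value of each list per library was also compared by an exact two-sided permutation test over the 56 ways to split the libraries into 3 and 5, whose smallest possible p is 0.0357. The fry test of limma, which asks only whether the genes of a list move on balance one way, served as an alternative.

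The genes named in the text follow a rule that was fixed with the lists. It takes Wwtr1, Yap1, Tead1 to Tead4, Ccn1 and Ccn2 whatever their values. It adds the 4 largest rises and the 4 largest falls among changed genes whose groups do not overlap and whose higher mean is at least 200, leaving out predicted genes and antigen receptor segments. From each list of main interest it takes the 2 changed members with the largest fold change and a higher mean of at least 50, and from every other list 1 such member. The rule gave 69 genes, of which 2 are not reported here, and other list members are named as examples chosen after their values were seen.

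The test was checked on simulated values for the same 14171 genes, with 200 genes changed and the genes of 1 further list moved for the list test. That is a far smaller share than the 62.3% of tested genes that changed in the data. It recovered 12%, 50%, 84% and 92% of genes changed by 1.5-fold, 2-fold, 4-fold and 8-fold in the comparison of 5 treated with 3 control libraries, and 6 genes, or 4.2% of the calls, were false. In the same simulation a list made of changed genes was called and 0 of the other lists were. The simulated genes varied independently of each other, so this check cannot show how camera or the false calls behave when genes are correlated. In the data the estimated correlation was 0.86 for the mitochondrially encoded transcripts and 0.65 for the cell cycle genes. With estimated correlations, 0 of the 29 lists called in the data passed. Alternatives covered pseudocounts of 0.5 and 10, no filter, a mean of at least 100, and scaling to equal totals, to equal upper quartiles or by quantiles. They also covered sample weights, a fit without the trend, a robust fit, a replicate block, each library left out in turn and stricter thresholds. Scaling to equal totals after leaving out Mup and mitochondrial genes was added after seeing the data. Tests by permutation and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.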

Results

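Poly-A RNA of mouse liver was sequenced in 8 libraries. The 3 control libraries came from untreated C57BL/6J mice. The 5 treated libraries, called TAZ-CCl4 libraries here, came from C57BL/6J mice that received TAZ S89A and CCl4. TAZ, encoded by Wwtr1, is a transcriptional coactivator restrained by the Hippo pathway, and S89A is a variant that lacks a phosphorylation site through which the pathway retains TAZ in the cytoplasm. CCl4 is a hepatotoxin used to cause chronic liver injury, and it was given 30 times, 3 times a week for 10 weeks. Normalised totals were 31.6 ± 2.96 M in the controls (SD, n = 3) and 13.3 ± 0.699 M in the TAZ-CCl4 libraries (SD, n = 5). The series title places the comparison in the study of a TAZ and TEAD2 pathway in hepatocellular carcinoma, and the design implies 1 comparison, TAZ-CCl4 against control libraries.

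Wwtr1 (mm10 chromosome 3, 57455649 to 57575910) rose from 367 ± 91.9 normalised counts in the controls (SD, n = 3) to 5733 ± 1873 in the TAZ-CCl4 libraries (SD, n = 5), a log2 fold change of 3.94 ± 0.24 (SE; limma, adjusted p = 1.00e-06). Among the TEAD transcription factors, which carry TAZ and YAP to DNA, Tead4 (chromosome 6, 128224288 to 128300823) rose from 6.10 ± 2.34 to 373 ± 108 and Tead2 (chromosome 7, 45215753 to 45233644) from 16.6 ± 6.23 to 226 ± 52.8. Tead1 (chromosome 7, 112679318 to 112906807) rose from 226 ± 90.5 to 1564 ± 602. Their log2 fold changes were 5.72 ± 0.29, 3.72 ± 0.29 and 2.79 ± 0.31. Tead3 (chromosome 17, 28331671 to 28350817) stood at 354 ± 30.3 and 383 ± 146 and did not pass the test (limma, adjusted p = 0.928), although it was higher at equal totals, with a log2 fold change of 1.28. Yap1 (chromosome 9, 7931999 to 8004596), which encodes the paralog of TAZ, fell from 1321 ± 161 to 882 ± 77.0 at the deposited scaling (log2 fold change -0.58 ± 0.13; limma, adjusted p = 0.00278) but was higher at equal totals, with a log2 fold change of 0.67. The gene-level values do not separate transcripts of the introduced construct from those of the endogenous Wwtr1 gene.

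Of the classical target genes, Ccn2 (chromosome 10, 24595442 to 24598683) rose from 118 ± 31.8 to 5105 ± 5044 (2876 without TAZ-CCl4 replicate 1) (log2 fold change 5.04 ± 0.55; limma, adjusted p = 2.85e-05), with single values of 14019, 3034, 1559, 3355 and 3557 in replicates 1 to 5. Ccn1 (chromosome 3, 145646976 to 145649981) stood at 1829 ± 228 and 2908 ± 2383 (1872 without TAZ-CCl4 replicate 1) and did not pass the test (log2 fold change 0.37 ± 0.47; limma, adjusted p = 0.515), although it passed at equal totals, with a log2 fold change of 1.62. Of 21 tested genes of the YAP/TAZ target signature, 18 rose, 1 fell and 2 did not pass, with a median log2 fold change of 2.38 (camera adjusted p = 6.27e-06; adjusted p = 0.296 with an estimated correlation). Ankrd1 (chromosome 19, 36111961 to 36120099), a muscle ankyrin repeat protein gene, rose from 15.1 ± 5.79 to 2209 ± 1412, and Fjx1 (chromosome 2, 102449366 to 102452499) from 1.83 ± 0.597 to 277 ± 211. Myof and Axl, a receptor tyrosine kinase gene, rose by 5.26 and 3.40 on the log2 scale. Nt5e, which encodes the ectonucleotidase CD73, fell, with a log2 fold change of -2.16. Of 21 Hippo pathway components, 13 rose, 1 fell and 7 did not pass, against 21 higher and 0 lower at equal totals (camera adjusted p = 0.00143; adjusted p = 0.342 with an estimated correlation). Vgll3 (chromosome 16, 65815257 to 65866368), a TEAD cofactor gene, rose from 3.82 ± 1.85 to 506 ± 292. The kinase genes Lats1 and Stk3 did not pass, at -0.14 and -0.10 on the log2 scale and 1.11 and 1.15 at equal totals. Adjusted over the list alone, 18 signature genes were higher and 1 lower, and 13 Hippo components were higher and 1 lower.

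**Figure D1:**
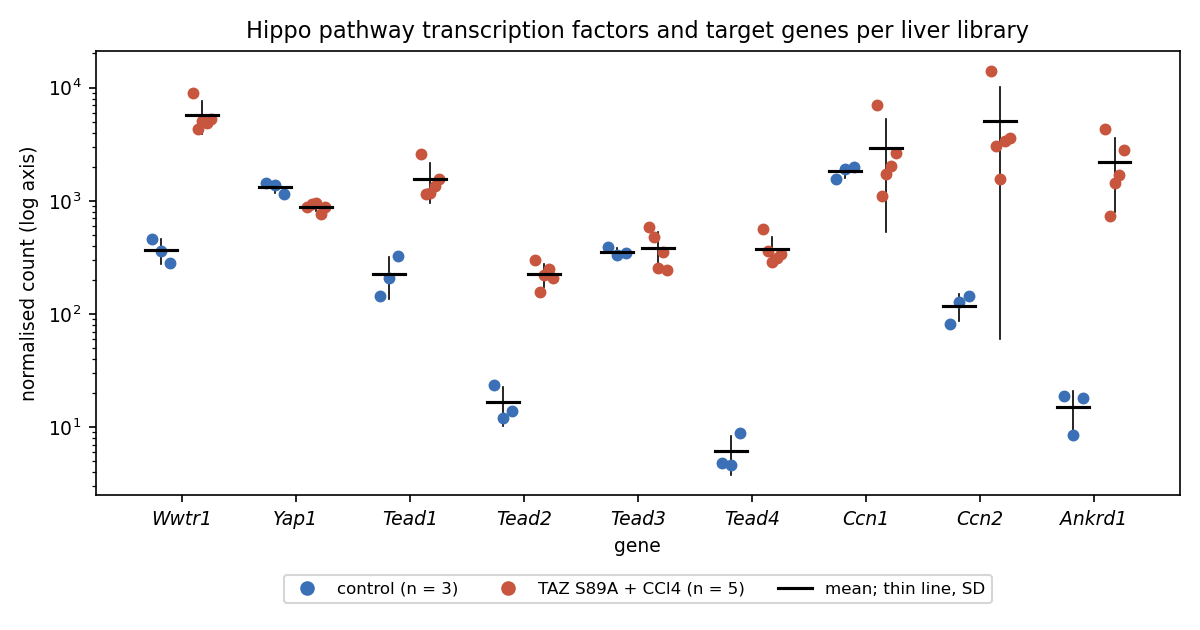
Normalised counts (log axis) of 9 genes in each of 3 control libraries (blue) and 5 TAZ-CCl4 libraries (red), with the mean as a thick line and the SD as a thin line. Wwtr1, Tead1, Tead2, Tead4, Ccn2 and Ankrd1 separate the groups, the values of Tead3 and Ccn1 overlap, and Yap1 lies lower in the TAZ-CCl4 libraries at the deposited scaling but has a log2 fold change of 0.67 at equal totals.

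Of 14171 genes tested, 8822 (62.3%) changed with limma at an adjusted p under 0.05, 4592 higher and 4230 lower. Of these, 3384 were more than 2-fold higher and 2251 more than 2-fold lower, and for 60.1% of tested genes the groups did not overlap, against 3.57% by chance. The median log2 fold change of all tested genes was 0.03 at the deposited scaling, 0.22 at equal upper quartiles, 1.26 at equal totals and 0.85 at equal totals without Mup and mitochondrial genes. The split moved with it, to 5467 higher and 3315 lower at equal upper quartiles, 10808 and 903 at equal totals, and 8912 and 1513 at equal totals without Mup and mitochondrial genes. Counts and directions below are relative to the deposited scaling unless another is named. Correlations of log2 values were 0.929 to 0.979 within groups and 0.7099 to 0.793 between them.

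The largest rises by the fixed rule were those of Igf2, Psca, Fgfbp1 and Spink1. Igf2 (chromosome 7, 142650766 to 142666816), a fetal growth factor gene, rose from 18.2 ± 8.37 to 57017 ± 53202 (log2 fold change 10.81 ± 0.95; limma, adjusted p = 6.33e-06), with values of 39055, 114439, 14045, 112853 and 4695 in replicates 1 to 5. Psca (chromosome 15, 74714839 to 74717069) was listed at 0 in the 3 controls and at 1805, 780.1, 364, 3486 and 662 in the TAZ-CCl4 libraries. Fgfbp1 (chromosome 5, 43978858 to 43981779), which encodes a secreted binding protein of fibroblast growth factors, rose from 1.23 ± 1.23 (0.612 without control replicate 2) to 1309 ± 503, and the trypsin inhibitor gene Spink1 (chromosome 18, 43728082 to 43737557) from 4.81 ± 4.11 (2.44 without control replicate 1) to 2565 ± 735. The largest falls were those of Mup7, Mup19, Mup15 and Mup17, genes of the major urinary proteins in a cluster on chromosome 4, which can share reads and are uncertain singly. Mup7 stood at 1925130, 992203 and 775264 in the controls and at 0, 0, 6.10, 0 and 7.77 in the TAZ-CCl4 libraries. Mup19 stood at 1148510, 357710 and 268765 and at 0, 0, 0, 0.445 and 1.34, Mup15 at 473075, 72246 and 44939 and at 0, 1.03, 0, 0 and 0, and Mup17 at 435551, 68522 and 42185 and at 0.903, 0, 0, 0 and 0. All Mup genes together took 15.7 ± 7.28% of the control signal (SD, n = 3) and 0.0511 ± 0.0621% of the TAZ-CCl4 signal (SD, n = 5; 0.00653% to 0.139% in single libraries).

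Genes of fetal liver, liver tumours and cell division rose together. Of 15 tested fetal liver and liver tumour markers, 13 rose and 2 did not pass, with a median log2 fold change of 4.58 (camera adjusted p = 6.27e-06; adjusted p = 0.166 with an estimated correlation). Afp, the fetal counterpart of albumin, rose from 30.3 ± 12.7 to 9607 ± 4703 (log2 fold change 8.19 ± 0.39) and the glypican gene Gpc3 from 21.3 ± 7.28 to 5355 ± 2535 (7.81 ± 0.39), while Ly6d and Robo1 did not pass. Of 26 cell cycle genes, 25 rose and only Tyms did not pass, with a median of 3.52 (camera adjusted p = 2.52e-07; adjusted p = 0.342 with an estimated correlation). Foxm1 (chromosome 6, 128362967 to 128376146), a transcription factor gene of the G2 phase, rose from 7.87 ± 2.63 to 274 ± 117, and the proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) from 41.7 ± 16.5 to 1019.6 ± 534. Of 16 p53 target genes, 8 rose, 3 fell and 5 did not pass, against 14 higher and 0 lower at equal totals, and the list was not called (camera adjusted p = 0.145). Phlda3 (chromosome 1, 135766119 to 135769136) rose from 18.4 ± 9.93 to 381 ± 41.9 and the cell cycle inhibitor gene Cdkn1a by 4.06 ± 0.34 on the log2 scale. Gdf15 fell, with a log2 fold change of -1.95 ± 0.42. Adjusted over the list alone, 13 fetal and tumour markers, 25 cell cycle genes and 8 p53 targets were higher and 0, 0 and 3 lower.

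Genes of the extracellular matrix and of signalling linked to it were higher. Of 24 structural matrix genes, 23 rose and only Dcn did not pass, with a median log2 fold change of 2.85 (camera adjusted p = 9.83e-09; adjusted p = 0.135 with an estimated correlation). Col1a1 (chromosome 11, 94936224 to 94953042) rose from 126 ± 17.3 to 2469 ± 796 and Thbs1 (chromosome 2, 118111876 to 118127133) from 25.1 ± 1.48 to 488 ± 309.5. Of 18 matrix remodelling enzymes and inhibitors, 17 rose and only Mmp9 did not pass (camera adjusted p = 3.44e-07; adjusted p = 0.102 with an estimated correlation). The protease inhibitor gene Timp1 (chromosome X, 20870166 to 20874735) rose from 2.74 ± 2.97 (1.17 without control replicate 1) to 205 ± 76.2, and the collagen crosslinking enzyme gene Lox by 5.76 ± 0.69 on the log2 scale. The control mean of Lox was 4.06, and 0.585 without control replicate 2. Of 14 TGF-beta signalling genes, 12 rose and Ltbp1 and Inhba did not pass (camera adjusted p = 1.90e-05; adjusted p = 0.166 with an estimated correlation). Tgfb2 (chromosome 1, 186622792 to 186705989) rose from 19.5 ± 3.14 to 644 ± 370.1. Of 13 Notch signalling genes, 12 rose and only Dll1 did not pass (camera adjusted p = 5.92e-04; adjusted p = 0.326 with an estimated correlation). The ligand gene Jag1 (chromosome 2, 137081456 to 137116644) rose from 133 ± 37.0 to 1918 ± 835. The 4 lists had 23, 17, 12 and 12 genes higher and 0 lower when adjusted over the list alone.

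Genes of differentiated hepatocyte functions were lower. Of 18 cytochrome P450 drug metabolism genes, 17 fell and only Por did not pass, with a median log2 fold change of -4.60 (camera adjusted p = 2.35e-08; adjusted p = 0.231 with an estimated correlation). Cyp2e1 (chromosome 7, 140763739 to 140774987), whose enzyme activates CCl4, fell from 165178 ± 10569 to 1174 ± 875 (log2 fold change -7.41 ± 0.46; limma, adjusted p = 1.09e-06), and Cyp4a14 (chromosome 4, 115486200 to 115496142) from 3782 ± 2483 to 41.3 ± 75.2 (7.84 without TAZ-CCl4 replicate 3). Of 18 bile acid synthesis and transport genes, 16 fell and 2 did not pass (camera adjusted p = 5.31e-08; adjusted p = 0.277 with an estimated correlation). The uptake transporter gene Slco1a1 (chromosome 6, 141907282 to 141946962) fell from 8305 ± 842 to 2.06 ± 2.09 (1.21 without TAZ-CCl4 replicate 3) and Cyp7b1 (chromosome 3, 18071950 to 18243338) from 10270.2 ± 1683 to 121 ± 57.9. Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -3.74 ± 1.56 and did not pass (limma, adjusted p = 0.0586). All 20 genes of the urea cycle and amino acid catabolism fell (camera adjusted p = 5.30e-08; adjusted p = 0.277 with an estimated correlation), among them Hal (chromosome 10, 93488768 to 93519304), from 11237 ± 1475 to 971 ± 589.6. Of 21 hepatocyte secreted protein genes, 16 fell and 5 did not pass, with a median of -1.35 (camera adjusted p = 3.51e-05; adjusted p = 0.342 with an estimated correlation). At equal totals 3 were higher and 5 lower, with a median of -0.10. After quantile normalisation 8 were higher and 6 lower, with a median of 0.49, and the call was lost (camera adjusted p = 0.378). Apoc3 (chromosome 9, 46232933 to 46235636) fell from 40209 ± 4207 to 1926 ± 1613 and Apoa2 (chromosome 1, 171225054 to 171226379) from 185628 ± 20442 to 17895 ± 6935. Alb stood at 1365900 ± 212188 and 617414 ± 128386 and did not pass (limma, adjusted p = 0.190; log2 fold change -1.16, and 0.09 at equal totals). Its group means lay further apart than these SDs. The test also uses a prior variance that follows the abundance of genes, so its p-value does not rest on the spread of Alb alone. Adjusted over the list alone, 17 P450 genes, 17 bile acid genes, 20 urea cycle genes and 16 secreted protein genes were lower and 0 higher. At equal totals, 16 P450 genes and 15 urea cycle genes were lower and 0 higher, and 13 bile acid genes were lower and 2 higher.

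Zonated and lipid genes followed. Of 18 perivenous and Wnt target genes, 14 fell, 2 rose and 2 did not pass (camera adjusted p = 2.58e-05; adjusted p = 0.135 with an estimated correlation). The glutamate transporter gene Slc1a2 (chromosome 2, 102658659 to 102790784) fell from 2183 ± 357 to 13.8 ± 14.9, and the glutamine synthetase gene Glul by a log2 fold change of -4.20 ± 0.26. Of 14 periportal genes, 11 fell, 2 rose and 1 did not pass (camera adjusted p = 0.00251; adjusted p = 0.296 with an estimated correlation), and the list was not called after quantile normalisation. Cyp2f2 (chromosome 7, 27119909 to 27133660) fell from 35292 ± 1089 to 1968 ± 1034. All 20 genes of fatty acid oxidation and ketogenesis fell (camera adjusted p = 5.28e-08; adjusted p = 0.277 with an estimated correlation), among them the peroxisomal thiolase gene Acaa1b (chromosome 9, 119148023 to 119157093), from 29521 ± 3906 to 1125 ± 626. Of 19 cholesterol synthesis genes, 17 fell and 2 did not pass (camera adjusted p = 9.29e-07; adjusted p = 0.320 with an estimated correlation). Hmgcs1 (chromosome 13, 119690379 to 119708260) fell from 16693 ± 3177 to 2003 ± 603 and Msmo1 (chromosome 8, 64718139 to 64733792) from 7266 ± 863 to 900.0 ± 247. Of 16 lipogenesis genes, 14 fell, Pnpla3 rose and Gpam did not pass (camera adjusted p = 8.27e-06; adjusted p = 0.166 with an estimated correlation). Thrsp (chromosome 7, 97412938 to 97417730) fell from 6178 ± 1071 to 83.0 ± 36.1. With p-values adjusted over the list alone, 15 perivenous, 11 periportal, 20 fatty acid oxidation, 17 cholesterol and 14 lipogenesis genes were lower, and 2, 2, 0, 0 and 1 higher. The same lists at equal totals had 12, 9, 12, 9 and 10 genes lower and 4, 3, 1, 3 and 4 higher.

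**Figure D2:**
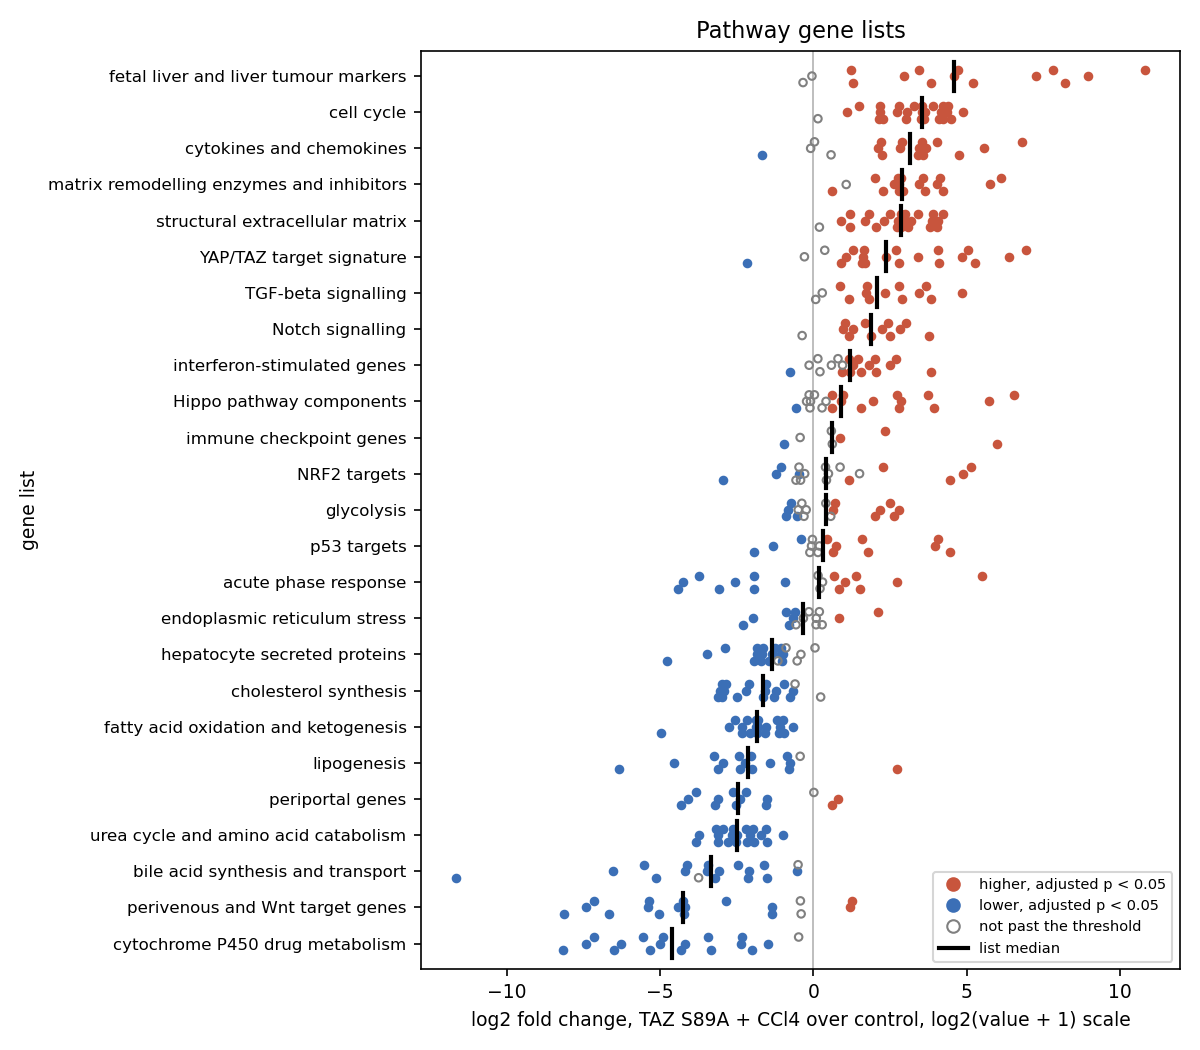
Log2 fold changes of the tested members of 25 pathway lists (x axis, TAZ-CCl4 over control, n = 5 and 3), 1 list per line, with the list median as a black bar. Filled points passed an adjusted p of 0.05 and open points did not. Medians run from 4.58 for fetal liver and tumour markers to -4.60 for cytochrome P450 genes, and those of the secreted proteins and of endoplasmic reticulum stress turn positive after quantile normalisation.

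Glycolysis and stress lists were not called at the deposited scaling, at which members of each moved both ways. Of 17 glycolysis genes, 7 rose, 4 fell and 6 did not pass, against 16 higher and 0 lower at equal totals and 12 higher and 0 lower after quantile normalisation (camera adjusted p = 0.667). Hk2 (chromosome 6, 82725025 to 82774454), which encodes a hexokinase of growing cells, rose from 19.5 ± 19.7 (8.27 without control replicate 2) to 102 ± 26.7 and Pkm by 2.62 ± 0.23 on the log2 scale. Gapdh fell at the deposited scaling, with a log2 fold change of -0.84 ± 0.19 that was 0.41 at equal totals. Of 18 NRF2 targets, 5 rose, 4 fell and 9 did not pass, against 14 higher and 1 lower at equal totals (camera adjusted p = 0.603). The carbonyl reductase gene Cbr3 (chromosome 16, 93683215 to 93690990) rose from 11.2 ± 3.95 to 436 ± 143. Both lists were called as higher after quantile normalisation. Of 15 endoplasmic reticulum stress genes, 2 rose and 6 fell, against 11 higher and 0 lower at equal totals (camera adjusted p = 0.280). Chac1 (chromosome 2, 119351229 to 119354381) fell from 161 ± 85.9 to 38.0 ± 31.5 (25.0 without TAZ-CCl4 replicate 1) (limma, adjusted p = 0.0190). The call was lost without control replicate 1 and without control replicate 3, with log2 fold changes of -1.96 and -2.05, and at equal totals. Of 18 acute phase genes, 7 rose and 8 fell, against 10 higher and 4 lower at equal totals (camera adjusted p = 0.747). Relative to other genes the acute phase list was called as lower at equal totals. Its median was 0.18 as deposited and its mean log2 difference -0.47. That difference rests in part on control replicate 1, whose mean log2 value over the list was 11.87 against 10.94 and 10.77 in control replicates 2 and 3. The control mean of Saa1, for example, was 3834, and 510 without control replicate 1. Lcn2 (chromosome 2, 32384633 to 32388252) rose from 363 ± 236 to 17812 ± 14441 (229 without control replicate 1 and 11601 without TAZ-CCl4 replicate 2). Orm1, which encodes a plasma glycoprotein, fell, with a log2 fold change of -4.25. Adjusted over the list alone, the glycolysis, NRF2, endoplasmic reticulum stress and acute phase lists had 7, 5, 2 and 7 genes higher and 6, 3, 6 and 8 lower.

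Inflammatory genes were higher. Of 18 tested cytokines and chemokines, 14 rose, Il18 fell and 3 did not pass, with a median log2 fold change of 3.13 (camera adjusted p = 3.06e-04; adjusted p = 0.342 with an estimated correlation). Ccl2 (chromosome 11, 82035571 to 82037453), which encodes a monocyte attractant, rose from 9.32 ± 5.65 (6.06 without control replicate 2) to 1298 ± 799, and Cx3cl1 (chromosome 8, 94772009 to 94782427) from 7.31 ± 0.565 to 397 ± 52.8. Of 19 interferon-stimulated genes, 12 rose and 6 did not pass, and Bst2 fell at the deposited scaling, with a log2 fold change of -0.78 that was 0.47 at equal totals (camera adjusted p = 0.00507; adjusted p = 0.599 with an estimated correlation). Ifit2 (chromosome 19, 34550694 to 34576419) rose from 40.1 ± 6.85 to 604 ± 165. At equal totals the calls of both lists were lost although more genes were higher, 16 cytokines and chemokines with a median of 4.12 and 18 interferon-stimulated genes with a median of 2.43. The median of all genes was 1.26 there. Of 7 tested immune checkpoint genes, 3 rose and 3 did not pass, against 6 higher and 0 lower at equal totals. Lgals9 fell at the deposited scaling, with a log2 fold change of -0.94 that was 0.31 at equal totals, and the list was not called (camera adjusted p = 0.347). Havcr2 (chromosome 11, 46454935 to 46481255), which encodes TIM-3, rose from 1.24 ± 1.25 (0.619 without control replicate 2) to 127 ± 32.8. Adjusted over the list alone, 14, 12 and 3 genes of these lists were higher and 1 of each lower.

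Markers of several other liver cell types were higher. Of 17 cholangiocyte and progenitor markers, 15 rose and Muc1 and Krt23 did not pass, with a median log2 fold change of 3.42 (camera adjusted p = 1.05e-06; adjusted p = 0.231 with an estimated correlation). Bicc1 (chromosome 10, 70922832 to 71159700) rose from 74.3 ± 22.5 to 4346 ± 1164, Sctr (chromosome 1, 120006894 to 120063536), the secretin receptor gene, from 2.75 ± 3.69 (0.650 without control replicate 3) to 107 ± 45.9, and Spp1 from 1855 ± 349.9 to 56155 ± 33776. Of 14 markers of recruited and lipid-associated macrophages, 13 rose and only Fabp5 did not pass, with a median of 3.94 (camera adjusted p = 1.20e-07; adjusted p = 0.123 with an estimated correlation). Trem2 (chromosome 17, 48346401 to 48354147) rose from 12.5 ± 7.77 to 580.1 ± 113 and Cx3cr1 (chromosome 9, 119901616 to 120069879) from 16.4 ± 2.97 to 1028 ± 372. Of 11 Kupffer cell markers, 5 rose and 2 fell (camera adjusted p = 0.135), with a median of 0.91 that was -0.02 after quantile normalisation and 0.23 to 1.45 with 1 library left out. The Kupffer list was called with a mean of at least 100. The general macrophage gene Csf1r (chromosome 18, 61100598 to 61132149) rose from 275 ± 84.2 to 4091 ± 1293. Timd4, a marker of resident cells, fell from 43.7 ± 7.74 to 5.12 ± 5.80 (3.40 without TAZ-CCl4 replicate 5). Of 16 stellate cell and myofibroblast markers, 7 rose, 2 fell and 7 did not pass, against 11 higher and 1 lower at equal totals (camera adjusted p = 0.170), with a median of 0.70 that was -0.16 after quantile normalisation. Vim (chromosome 2, 13573927 to 13582826) rose from 216 ± 45.0 to 3405 ± 1249. Lrat, a gene of quiescent stellate cells, had a log2 fold change of -0.65, and 0.59 at equal totals, and did not pass. When adjusted over the list alone, the 4 lists had 15, 13, 5 and 7 genes higher and 0, 0, 2 and 2 lower.

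All 6 tested neutrophil markers rose (camera adjusted p = 0.00762; adjusted p = 0.342 with an estimated correlation), among them S100a8 (chromosome 3, 90668978 to 90670035), from 8.86 ± 0.594 to 92.0 ± 35.2. Of 15 T and NK cell markers, 10 rose and 5 did not pass (camera adjusted p = 0.00552; adjusted p = 0.342 with an estimated correlation). The T cell kinase gene Lck (chromosome 4, 129548344 to 129573641) rose from 11.8 ± 5.48 to 64.6 ± 18.5, Thy1 (chromosome 9, 44043384 to 44048579) from 47.4 ± 2.32 to 247 ± 74.6 and Cd8a from 4.42 ± 3.95 (2.84 without control replicate 2) to 43.9 ± 16.4, while Cd4 did not pass. Of 9 dendritic cell markers, 5 rose and 4 did not pass (camera adjusted p = 0.0446; adjusted p = 0.342 with an estimated correlation). Cd74 (chromosome 18, 60803848 to 60812652) rose from 764 ± 294 to 10854 ± 3302. The list members with the lowest log2 fold changes, Clec9a, Zbtb46 and Siglech, stood at -1.05, 0.34 and 0.78. The calls of these 3 lists were lost at equal totals, although 6, 13 and 8 genes were higher there with medians of 3.98, 2.79 and 3.13, and after quantile normalisation, with 3, 6 and 4 genes higher. That of the dendritic list was lost also at equal upper quartiles and without TAZ-CCl4 replicate 3, 4 or 5, with medians of 1.60, 1.94 and 1.85. Of 9 B and plasma cell markers, 3 rose and 1 fell, against 6 higher and 0 lower at equal totals and 1 higher and 4 lower after quantile normalisation (camera adjusted p = 0.724). The antibody joining chain gene Jchain (chromosome 5, 88519809 to 88527891) rose from 38.5 ± 12.7 to 511 ± 349. The B cell gene Pax5 fell, with a log2 fold change of -2.15 ± 0.75. Of 12 vascular endothelial markers, 9 rose and 3 did not pass (camera adjusted p = 0.00713; adjusted p = 0.342 with an estimated correlation), a call that was lost at equal totals, although 12 of 12 were higher there with a median of 2.43. Aplnr (chromosome 2, 85136225 to 85139923) rose from 1.02 ± 1.76 (0 without control replicate 3) to 67.0 ± 54.8. Of 14 sinusoidal endothelial markers, 8 fell and 1 rose, against 5 higher and 1 lower at equal totals (camera adjusted p = 0.127). Relative to other genes the list was called as lower at equal totals, where its median was -0.08 against 1.26 for all genes, and without control replicate 1, where its median was -1.53. The sinusoidal lectin gene Clec4g (chromosome 8, 3707064 to 3720651) fell from 474 ± 194 to 95.0 ± 65.9, a call that was lost at equal totals, with a log2 fold change of -1.41. When adjusted over the list alone, the neutrophil, T and NK, dendritic, B and plasma, vascular and sinusoidal lists had 6, 10, 5, 2, 9 and 1 genes higher and 0, 0, 0, 1, 0 and 8 lower.

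**Figure D3:**
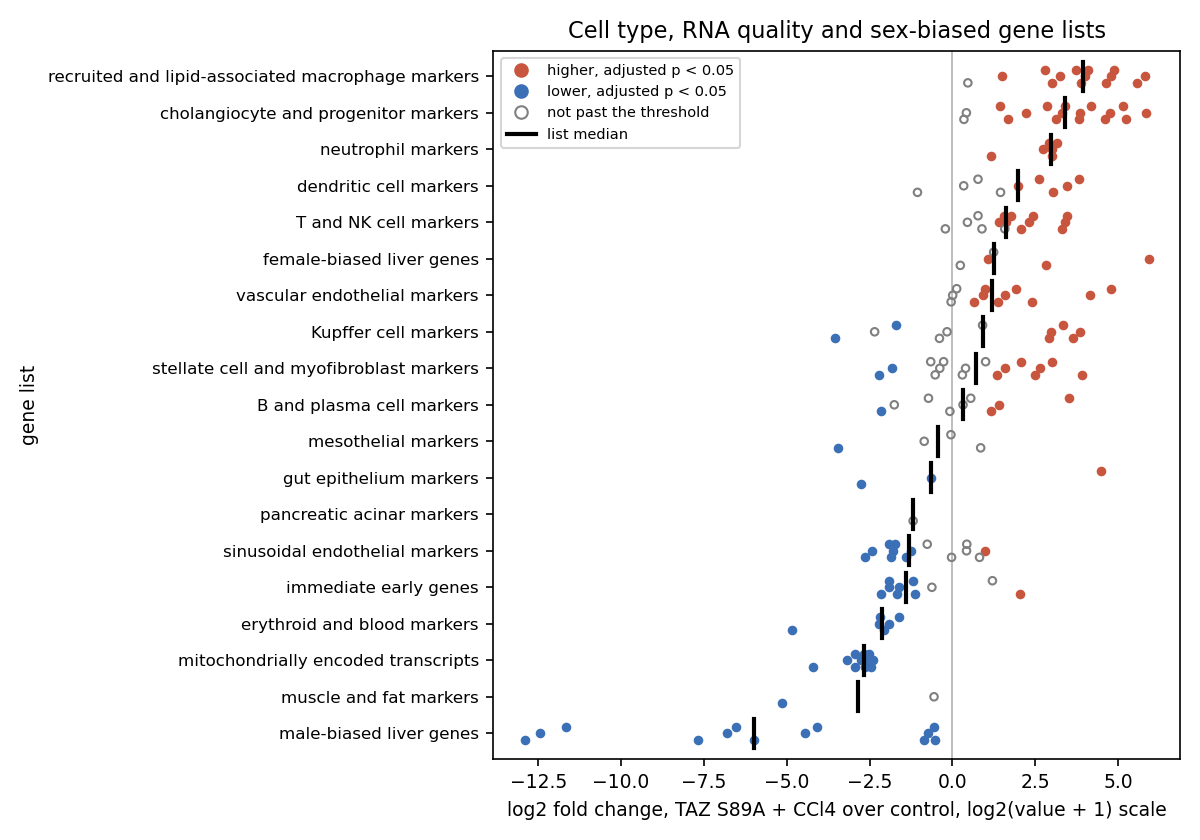
Log2 fold changes of the tested members of 19 lists of cell type, RNA quality and sex-biased genes (x axis, TAZ-CCl4 over control, n = 5 and 3), with the list median as a black bar, filled points for an adjusted p under 0.05 and open points for the rest. Medians run from 3.94 for recruited macrophages to -6.00 for male-biased genes, and the split of sinusoidal endothelial markers turns from 1 higher and 8 lower to 5 higher and 1 lower at equal totals.

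Lists that track the animal, the blood content and RNA quality moved with the groups as well. All 13 male-biased liver genes fell, against 9 lower and 3 higher at equal totals, with a median log2 fold change of -6.00 (camera adjusted p = 2.17e-07; adjusted p = 0.231 with an estimated correlation), but the Y-linked members Ddx3y, Eif2s3y, Uty and Kdm5d fell by less than 1 on the log2 scale and had 3 higher and 0 lower at equal totals. The steroid dehydrogenase gene Hsd3b5 (chromosome 3, 98618634 to 98630252) was listed at 0 in the 5 TAZ-CCl4 libraries and stood at 8184, 7033 and 7969.6 in the controls. Of 5 tested female-biased genes, 3 rose and 2 did not pass (camera adjusted p = 0.150). All 11 listed mitochondrially encoded transcripts fell (camera adjusted p = 8.27e-06; adjusted p = 0.342 with an estimated correlation), and their call was lost after quantile normalisation. The transcript mt-Nd6 (mitochondrial genome, 13552 to 14070) fell from 1430.1 ± 629 to 74.7 ± 21.7. All mitochondrial transcripts took 12.9 ± 1.32% of the control signal (SD, n = 3) and 4.87 ± 1.25% of the TAZ-CCl4 signal (SD, n = 5). All 6 erythroid and blood markers fell (camera adjusted p = 0.00738; adjusted p = 0.277 with an estimated correlation), among them Alas2 (chromosome X, 150547375 to 150570638), from 2816 ± 187 to 103 ± 38.9. At equal totals 1 of 6 was lower and the median was -0.88, and the list was still called as lower relative to other genes (camera adjusted p = 1.65e-06). Of 10 immediate early genes, 7 fell and 1 rose, against 2 higher and 1 lower at equal totals (camera adjusted p = 0.0411; adjusted p = 0.565 with an estimated correlation), a call that was lost without control replicate 2 or 3 or TAZ-CCl4 replicate 3 or 4, with medians of -1.33 to -1.40, and after quantile normalisation. Ier2 (chromosome 8, 84661331 to 84662852) fell from 3546 ± 454 to 806 ± 193. With p-values adjusted over the list alone, 13 male-biased, 11 mitochondrial, 6 erythroid and 7 immediate early genes were lower and 3 female-biased genes higher.

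Few markers of neighbouring organs passed the filter. Of 4 mesothelial markers, only Upk3b fell, against 1 higher and 1 lower at equal totals (camera adjusted p = 0.569). Of 3 gut epithelium markers, 2 fell and Cdh17 rose, against 2 higher and 1 lower at equal totals (camera adjusted p = 0.667). Fabp2 (chromosome 3, 122895072 to 122899506), which liver also expresses, fell from 1392 ± 174 to 238 ± 140.1. The median of the gut list was -0.65 and its mean log2 difference 0.36. Of 2 muscle and fat markers, Cfd (chromosome 10, 79890853 to 79892655) was listed at 0 in the 5 TAZ-CCl4 libraries and at 93.1, 56.998 and 7.07 in the controls, and the other, Mylpf, did not pass (camera adjusted p = 0.253), and the list was called as lower at equal totals. The 1 tested pancreatic acinar marker, Cela2a, did not pass. With p-values adjusted over the list alone, the counts were 1 lower for the mesothelial list, 1 higher and 2 lower for the gut list, 1 lower for the muscle and fat list and 0 for the acinar list.

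Of the 43 lists tested by camera, 29 were called, 16 higher and 13 lower, and 0 with an estimated correlation. The fry test called 36, and for 36 lists the exact two-sided permutation test gave its smallest possible p of 0.0357. Library project and group coincide, TAZ S89A and CCl4 were given together, and the controls were untreated. The effects of construct, toxin, injection procedure, repeated dosing and project therefore cannot be told apart in these data. The labels do not say whether a liver piece held tumour or surrounding tissue.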

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

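No test in this part was chosen after its result was seen. For 119 values, namely the named genes, the list means and the library measures, the 5 TAZ-CCl4 libraries were searched for 1 that lay apart from the other 4 by more than Dixon's test allows for 5 values. This was so for 9 values, and chance gives about 1 in 20.

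TAZ-CCl4 replicate 1 had the highest Wwtr1, 9021 normalised counts against 4339 to 5299 in the other replicates. Its mean log2 value over the Hippo pathway components, a list that contains Wwtr1, was 9.855 against 9.307 to 9.457. Its mean over the lipogenesis genes was 9.084 against 9.438 to 9.578. Its Mup17 value was 0.903 where the other 4 were listed at 0, a value of about 1 read.

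In TAZ-CCl4 replicate 2, Fgfbp1 stood at 459 normalised counts against 1248 to 1660 in the others. Its Mup15 value was 1.03 where the other 4 were listed at 0, also a value of about 1 read.

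TAZ-CCl4 replicate 4 had an estimated depth of 33.9 M reads against 12.4 to 14.4 M in the others. Its mean log2 value over the acute phase genes was 9.773 against 10.80 to 11.15, and its mean over the endoplasmic reticulum stress genes was 9.643 against 10.45 to 10.64. Without this replicate, 8702 genes were changed in place of 8822.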

How the results depend on the processing

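Scaling to equal totals without Mup and mitochondrial genes was chosen after the data were seen, and every other setting was laid down beforehand. Of the tests laid down beforehand, edgeR and DESeq2 on recovered reads were not run because whole reads were not recovered. The count of 8822 changed genes ran from 6676 to 11711 over the other settings for all 8 libraries, apart from a minimum fold change of 2, which left 5635, 3384 higher and 2251 lower, by its construction. Leaving out 1 library in turn gave 7623 to 8863 genes, 4047 to 4575 of them higher and 3576 to 4288 lower, and 27 to 30 lists.

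The direction of calls depended on scaling. At equal totals, 10808 genes were higher and 903 lower, and 2475 of the 8822 genes called at the deposited scaling changed sign, called again or not. At equal totals without Mup and mitochondrial genes, 8912 were higher and 1513 lower. A mean of at least 100 left 2946 genes higher and 3730 lower, with fewer genes tested. Yap1 reversed to a log2 fold change of 0.67 at equal totals and 0.25 at equal totals without Mup and mitochondrial genes, since these scalings raise all TAZ-CCl4 values alike. The median of the hepatocyte secreted proteins reversed to 0.49 after quantile normalisation, and the cause was not tested.

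Of results for named genes, 1359 kept the side of the threshold, and their direction where called, 6 lost the call and 4 gained one. Tead3, not called, went from a log2 fold change of 0.03 to -0.03 after quantile normalisation. Of results for lists, 869 kept the side of the threshold, and their camera direction where called, 55 lost the call and 15 gained one. Of the losses, 29 came with the estimated correlation, 6 at equal totals and 6 after quantile normalisation. Of the gains, 7 came with the fry test, which asks a different question. Why calls moved at the other settings was not tested. Lists that were not called could change direction, as the endoplasmic reticulum stress list did after quantile normalisation, from lower to higher. With an estimated correlation, 0 of the 29 camera calls passed, which says that the calls rest on the preset value. The numbers of the libraries did not pair them: deviations of same-numbered libraries correlated at -0.07, -0.06 and -0.09. With the number as a replicate block, on the 6 libraries that share one, 7366 genes changed, 3791 higher and 3575 lower, and 28 lists were called.

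The grouping of the libraries by chance was examined over all 56 splits into 3 and 5. Only the real split gave 8822 changed genes, and the highest other gave 2. Every other split mixes the groups, so their difference widens the spread within its sides and leaves few calls. The low counts there were bound to follow and do not exclude chance. For lists, 7 of the 56 splits gave as many as the real 29, and the highest other gave 31, so chance is not excluded for the number of lists. Of those 7, 3 were among the 10 splits with 0 controls in the group of 3, 3 among the 15 with 2 controls, and 0 among the 30 with 1 control. Splits with 0 or 2 controls there still carry part of the real difference, so they do not measure chance for the lists either. The depth limits low genes most: 1 read was worth 0.365 to 1.90 normalised counts.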

Other observations

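The tests of the authors' scaling, of the library projects and of mixed control RNA were chosen after the results were seen, and the nuclear respiratory chain list was drawn up after the mitochondrial share was seen but before the values of its own genes were. Gene families were formed afterwards from shared symbol stems, 255 with at least 8 tested genes. Several families, some with members in the fixed lists, moved together, with camera p-values adjusted over the 255 families, none of which passed with an estimated correlation. Of 11 Ms4a genes, which encode membrane proteins of immune cells, 10 rose, with a median log2 fold change of 4.86 (camera adjusted p = 5.10e-04; adjusted p = 0.438 with an estimated correlation). Ms4a7 rose by 5.33 ± 0.31 and Ms4a4a by 6.89 ± 0.33 on the log2 scale. Of 11 Toll-like receptor genes, 9 rose and Tlr5 fell (camera adjusted p = 9.26e-03; adjusted p = 0.507 with an estimated correlation). Of 13 Adamts protease genes, 12 rose and Adamts13 fell at the deposited scaling, with a log2 fold change of -0.94 that was 0.30 at equal totals (camera adjusted p = 1.88e-03; adjusted p = 0.438 with an estimated correlation). Of 10 Cdkn genes, most of them cell cycle inhibitors, 8 rose and 1 fell at the deposited scaling (camera adjusted p = 4.26e-02; adjusted p = 0.438 with an estimated correlation). Cdkn2a, a senescence marker, stood at 0, 1.26 and 0 in the controls and at 29.5, 21.6, 80.9, 32.8 and 66.4 in the TAZ-CCl4 libraries.

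Among families that fell, 14 of 16 carboxylesterase (Ces) genes were lower, with a median log2 fold change of -2.99, against 9 lower and 2 higher at equal totals (camera adjusted p = 1.09e-04; adjusted p = 0.438 with an estimated correlation), and Ces1e and Ces2c fell, with log2 fold changes of -4.73 ± 0.45 and -4.38 ± 0.43. Of 19 glucuronosyltransferase (Ugt) genes, 17 fell and 2 rose, with a median of -3.71, against 14 lower and 4 higher at equal totals (camera adjusted p = 1.08e-04; adjusted p = 0.494 with an estimated correlation). Paralogs in both families can share reads. Of 50 mitochondrial ribosomal protein (Mrpl) genes, 45 were lower with a median of -0.89 at the deposited scaling (camera adjusted p = 6.43e-10; adjusted p = 0.438 with an estimated correlation). At equal totals, however, 24 were higher and 0 lower. Of 16 peroxin (Pex) genes, 15 were lower at the deposited scaling (camera adjusted p = 2.09e-05; adjusted p = 0.438 with an estimated correlation), but 4 were higher and 3 lower at equal totals. Of 109 olfactory and vomeronasal receptor genes, 56 were lower and 7 higher at the deposited scaling, 6 lower and 24 higher at equal totals, and 89 lower and 3 higher after quantile normalisation.

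Markers of other liver cell types were higher while hepatocyte genes were lower, so a smaller share of hepatocytes in the pieces is a candidate explanation. A smaller share alone raises all other types alike, but the medians of 10 cell type lists ranged over 5.25 on the log2 scale, from 3.94 for recruited macrophages to -1.32 for sinusoidal endothelium. The mean log2 value per library of these lists went from 6.02 ± 0.196 to 9.77 ± 0.207 and from 7.76 ± 0.476 to 6.82 ± 0.561 (SD, n = 3 and 5). This argues against a smaller share as the whole cause. The permutation p of 0.0003 came from shuffling genes between lists, which treats genes as independent and does not measure the spread between libraries. A smaller share also lowers hepatocyte genes alike, but the P450 median lay -3.24 from the secreted protein median, which argues against it too. By library, the mean log2 values of these lists went from 14.16 ± 0.208 to 9.70 ± 0.76 and from 16.07 ± 0.0169 to 14.51 ± 0.378 (SD, n = 3 and 5). The permutation p of 2e-05 again came from shuffled genes and has the same limit. A part played by hepatocyte share stays open, as do a change within hepatocytes and the effects of TAZ S89A and CCl4, which the design names and these tests do not separate.

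Mitochondrially encoded transcripts were lower. The authors' scaling is argued against as the whole cause, since the median of 13 mitochondrial genes was -1.40 at equal totals, with 13 of 13 lower, although after quantile normalisation 6 of 13 were lower and the median shrank from -2.66 to -0.73. Fewer mitochondria or fewer cells rich in them could lower nuclear respiratory chain genes too: these had a median of -1.44, with 40 of 40 lower, or 54.3% of the mitochondrial fall, but 13.5% at equal totals. Whether fewer mitochondria or fewer such cells account for the pattern therefore depends on the scaling and stays open. Shuffling genes between the sets gave a permutation p of 1e-05, the smallest the permutations can give. That p treats genes as independent, although the 11 listed mitochondrial transcripts had an estimated correlation of 0.86, and does not measure the spread between libraries. As 0 library projects held both groups, a difference between projects cannot be told apart from the group.

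Mup3, Mup20 and Mup22 differed among TAZ-CCl4 libraries: Mup3 stood at 28.4, 24.6, 2623, 32.2 and 1456, Mup20 at 937, 834, 14835, 876 and 10637 and Mup22 at 1.81, 0, 1661, 0 and 568 in replicates 1 to 5. Control RNA mixed into replicates 3 and 5 is a possible explanation and would need 0.817% and 0.454% of control signal to give their Mup3. Hsd3b5, abundant in the controls, was listed at 0 there, and with 3 reads as an upper limit it allowed at most 0.0424% in either, which argues against mixing. Replicates 3 and 5 were also the most alike of the TAZ-CCl4 pairs over all tested genes. Their log2 values correlated at 0.974, and those of the next pair, replicates 1 and 5, at 0.955. Replicates 3 and 5 differed by 6.56 times the variance of counting noise, and replicates 1 and 5 by 13.2 times. The likeness of replicates 3 and 5 is thus not limited to Mup genes, and whether they are independent samples is not known. A sharing of reads between Mup paralogs and a difference between the samples themselves stay open. A comparison of Mup paralog pairs was made and dropped, because it set against each other libraries picked by their Mup values, and it is not reported here.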
